A study of Mus musculus with 2 samples.

How the data were processed

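The data are chromatin immunoprecipitation sequencing (ChIP-seq) peak lists for H3K4me3, histone H3 trimethylated at lysine 4, from midbrain of newborn mice (postnatal day 0). Per the labels, the 2 samples are biological replicates of 1 group, both from pooled male and female mice of strain B6NTac;B6NCrl/Lap. Replicate 1 was made from the midbrains of 15 mice, and for replicate 2 the labels say only that mice were pooled. The labels record a size range of 300 to 500 for both libraries, with no unit.

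The authors deposited 4 peak lists in mm10 coordinates. Per the deposited notes, each replicate has its own list made from its own alignments, the pooled list was made from the alignments of both replicates, and the replicated list was derived from the pooled list together with both replicates' lists. The aligner, the peak caller, its threshold, the control and the rule for keeping a replicated peak are not given in the sources used here. Each list gives the peak's coordinates and the offset of its summit. The authors' display score was not used. The deposited signal value is the peak's enrichment as the authors' caller gave it, and what it is relative to is not given in the sources used here. The deposited −log10 p-value and −log10 q-value are the caller's own. These 3 values belong to the authors and to 1 list, so they were used only to rank, describe, filter or match within a list. A filter of the authors on p or q can set how far a list reaches into weak signal, and reads that match several places in the genome can be lost or kept, which bears on repeated gene families. No read counts came with the lists, so the sequencing depth of the samples is unknown.

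Genes and transcript starts were taken from GENCODE release M21 for GRCm38, the same assembly as mm10. No peak of any list ended past a chromosome end of the GRCm38 sequence. Coordinates are 1-based. Scaffolds were left out wherever the annotation was used, which removed 14 replicated peaks. A gene was called marked when a peak overlapped the 1 kb on either side of any of its annotated transcript starts (TSS). Its covered length was the number of bases in peaks within 5 kb of a TSS, taking the start with the most, so the highest possible value is 10001 bp. A domain was a run of peaks joined across gaps of up to 1 kb. Promoters were called CpG-rich at an observed-to-expected CpG ratio of at least 0.6 and a GC content of at least 50% in the 1 kb centred on the gene's 5′-most start.

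Peaks of the replicates were called shared when at least 50% of either peak's length overlapped. Shares were set beside 100 random placements of the peaks on their own chromosomes, in one-sided permutation tests. The smallest p that 100 placements can give is 0.0099. Marked shares were compared with two-sided Fisher's exact tests. List medians of covered length were compared with 10000 random lists of marked protein-coding genes in two-sided permutation tests, whose smallest p is 0.0002. Both families were adjusted by the Benjamini-Hochberg method, over 22 gene lists for marked shares and over the 18 lists with at least 5 marked members for covered length. These tests run across genes of 1 group. Genes are not independent replicates, so the p-values describe how a list stands among genes and not a difference between conditions. Intervals are exact 95% binomial intervals and cover counting error only.

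The gene lists, the tests, most alternative settings and the rule for naming genes were fixed before the data were examined. The lists hold markers of neuron classes, progenitors, glia, microglia, vessels and blood cells, regional and non-neural transcription factors, genes of other tissues, and gene families. Only protein-coding members were tested, 15 of the 18 imprinted genes among them. Some genes are in more than 1 list, so the lists are not fully separate. This holds for 5 of the 18 midbrain, 3 of the 12 GABAergic, 2 of the 9 serotonergic and 2 of the 10 glutamatergic genes, and for 1 or 2 genes of some other lists. The rule names the genes at the 20 longest domains, the 3 marked members with the greatest covered length in each list of named members, and up to 3 unmarked members in alphabetical order. A gene at a longest domain also needed a peak at its start in both replicates' lists. The rule also names the 5 distal peaks with the highest signal value and the 3 peaks with the highest signal value found in only 1 replicate. Genes outside this rule are named in a few places and were then chosen after their values were seen.

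Alternatives were each replicate's own list, the pooled list, −log10 q minimums of 2, 5 and 20, other overlaps, windows, merging distances and starts, and CpG-rich promoters only. The tests were checked on simulated data. A simulated overlap of 69.8% was recovered as 69.8%. A list raised from 60 to 100% and a list lowered from 60 to 15% were called in 20 of 20 simulations each, and an unchanged list in 0 of 20. Genes were marked independently of each other in these simulations. Smaller shifts and neighbouring genes with shared peaks were not simulated. A list lengthened through CpG number alone was called in 2 of 20 simulations after matching on CpG number, and a list doubled beyond it in 20 of 20. Simulated lengths were made from the CpG number around the 5′-most start, the same number used for matching. This check therefore does not cover genes whose covered length comes from another start. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, bedtools 2.31.1, samtools 1.23.1, pysam 0.24.0 and matplotlib 3.10.9.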

Results

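H3K4me3, a histone mark found at active and poised promoters, was mapped in the midbrain of newborn mice, in 2 biological replicates of 1 group and with no second condition. Replicate 1 had 27410 peaks covering 40.1 Mb and replicate 2 had 25539 peaks covering 32.3 Mb. The mean was 26474.5 ± 1323 peaks (SD, n = 2) and 36.2 ± 5.53 Mb (SD, n = 2), and the median peak width was 1115.75 ± 93.0 bp (SD, n = 2). The authors' list of replicated peaks held 22478 peaks covering 38.4 Mb, with a median width of 1514 bp and a longest peak of 18982 bp. It was used for all values on genes unless a replicate is named. The number of reads behind each list is unknown, so the precision that depth gives could not be stated.

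The design allows 1 comparison between samples, that of the replicates. Promoters agreed closely: 14233 protein-coding genes had a peak at a TSS in both replicates, 341 in replicate 1 only and 45 in replicate 2 only. Among those marked in replicate 1 only were Ddc, which encodes the decarboxylase of dopamine and serotonin synthesis, and Tbr1, a transcription factor of cortical glutamatergic neurons. Hoxa11, a patterning gene of the posterior body and limbs, was marked in replicate 2 only. The share of protein-coding genes marked was 66.4% in replicate 1 and 65.1% in replicate 2, a mean of 65.8% ± 0.954 (SD, n = 2). Of the clustered protocadherins, neuronal adhesion molecules encoded in gene arrays on chromosome 18, replicate 1 marked 89.5% and replicate 2 marked 56.1%. Across the 14233 genes marked in both, covered length correlated with a Spearman coefficient of 0.953 and a Pearson coefficient of 0.964. These are correlations across genes, which are not independent replicates. Covered length was greater in replicate 1 at 93.7% of these genes, with a median ratio of 1.16.

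Replicate 2 met 73.6% of the replicate 1 peaks (20179 of 27410, 95% interval 73.1 to 74.1%), against a mean of 2.01% for random placements. Replicate 1 met 92.2% of the replicate 2 peaks (23551 of 25539, 95% interval 91.9 to 92.5%), against a mean of 2.14%. Both shares passed the permutation test at p = 0.0099, the smallest that 100 placements can give. The placements were not held to promoters, where most peaks of both lists lie. The test therefore cannot show agreement beyond a shared location at promoters. Bases in peaks of both lists came to 31.4 Mb, 76.8% of the bases in peaks of either list. Peaks found in only 1 replicate were narrow and weak within their own list. In replicate 1 their median width was 308 bp against 1676 bp for shared peaks, and their median signal value was 3.11 against 30.4. In replicate 2 the widths were 224 and 1181 bp and the signal values 3.34 and 15.9. With each list ranked and divided into 10 equal parts, all peaks in the strongest 5 parts of the replicate 1 list were shared, against 9.16% in the weakest part. The weakest part of the replicate 2 list was shared at 59.3%. Among peaks with no overlapping base in the other list, the highest signal value in replicate 1 was 9.67. It was reached at 24305046 to 24305758 on chromosome 11, an intergenic position 163 kb from Bcl11a, and at 39588187 to 39588718 on chromosome 7, at a transcript start of Gm2058. The next, 9.26, was at 128444032 to 128444636 on chromosome 5, at a start of Gm42495. In replicate 2 the highest were 5.58 at 84769924 to 84770637 on chromosome 8, in an intron of Nfix, 5.55 at 65196700 to 65197042 on chromosome 9, within Parp16, and 5.29 at 40397057 to 40397300 on chromosome 9, in an intron of Gramd1b.

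**Figure D1:**
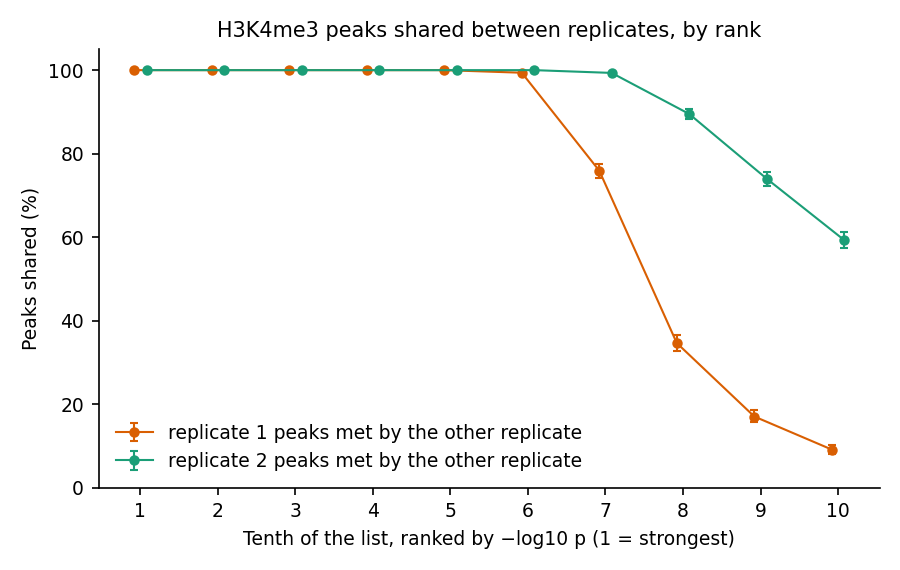
Percent of each replicate's H3K4me3 peaks met by the other replicate (y axis) in each of 10 equal parts of its own list ranked by the authors' −log10 p (x axis, 1 = strongest), with exact 95% binomial intervals as bars. All peaks of the strongest 5 parts are shared in both lists, and the weakest part falls to 9.16% in replicate 1 and 59.3% in replicate 2.

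Replicated peaks lay mainly at promoters. Of the 22464 on chromosomes, 71.7% (16110, 95% interval 71.1 to 72.3%) overlapped the 1 kb around a TSS, against a mean of 10.5% for random placements (permutation p = 0.0099, the smallest possible). Peaks at a TSS had a median width of 1894 bp. A further 4.67% overlapped an exon, 10.7% an intron and 12.9% no gene. Peaks more than 5 kb from every TSS made up 16.3% (3656, 95% interval 15.8 to 16.8%), against 73.7% for random placements, and their median width was 637 bp. Of these 3656 peaks, 2241 were intergenic, 1028 intronic and 387 exonic. The distal share fell to 9.16% among peaks with a −log10 q of at least 20, and rose to 24.8% when distance was measured to the 5′-most start of each gene.

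The distal peak with the highest signal value, 55.9, lay at 171037630 to 171039235 on chromosome 1, an intergenic position 18.7 kb from the nearest protein-coding start, that of the Fc receptor gene Fcgr4. The next lay at 165280811 to 165284403 on chromosome 1, 11.4 kb from Gpr161, which encodes a receptor of primary cilia. Another, at 7163319 to 7166852 on chromosome 19, was in an intron of Macrod1. The others were an intergenic peak at 22080279 to 22081666 on chromosome 17, nearest to the zinc finger gene Zfp947, and an intronic peak of Phactr1 at 42915865 to 42917694 on chromosome 13. Signal values of these 5 ran from 48.4 to 55.9, and the median of all distal peaks was 5.52.

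Of 21938 protein-coding genes, 14400 were marked, a share of 65.6% (95% interval 65.0 to 66.3%). CpG-rich promoters were marked at 98.8% (9622 of 9742) and CpG-poor promoters at 39.2% (4778 of 12196). The odds ratio was 124, and the two-sided Fisher's exact p was too small for the software to represent. X-linked genes were marked at 51.7% (490 of 948, 95% interval 48.5 to 54.9%) and autosomal genes at 66.8% (13906 of 20807), a difference of -15.1 percentage points (Fisher's exact p = 5.19e-21). X-linked genes had fewer CpG-rich promoters, 24.1% against 45.7% of autosomal genes. Without olfactory and vomeronasal receptor genes the X-linked difference was -19.7 points, at 52.2% against 71.9% (Fisher's exact p = 2.50e-35). In alternatives added after the data were seen, the difference was -0.995 points among CpG-rich promoters (Fisher's exact p = 0.205). Among CpG-poor promoters it was -2.82 points (Fisher's exact p = 0.136). Among genes CpG-poor at every start it was 1.06 points, also without passing. The call was lost in these classes. The CpG-rich class held 1 receptor gene, and the genes CpG-poor at every start held 1465. CpG-poor genes without receptors were not tested, so CpG class was not shown to account for the difference.

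The gene lists ask which cell types and developmental programmes carried the mark in this tissue. Every member was marked in 6 of the 22 lists. These were the midbrain regional transcription factors and organiser signals (18 of 18), the GABAergic and glycinergic neuron genes (12 of 12), the pan-neuronal genes (20 of 20), the neural progenitor genes (18 of 18), the housekeeping reference genes (16 of 16) and the immediate early genes (14 of 14). Their adjusted Fisher's exact p against other protein-coding genes ran from 0.00204 to 0.0225. Ribosomal protein genes (80 of 83, adjusted Fisher's exact p = 1.98e-10), forebrain transcription factors (17 of 18, adjusted p = 0.0225) and imprinted genes (14 of 15, adjusted p = 0.0490) were also marked more often than other genes. The unmarked ribosomal genes were Rpl10l, Rpl39l and Rpl3l, named as paralogs of the ubiquitous genes. Ndn, an imprinted gene of neurons, had no peak at its start but 1839 bp of peaks within 5 kb. Among CpG-rich promoters alone 98.8% of all genes were marked, a share so high that none of these 9 lists could pass above it. Among genes CpG-poor at every start, chosen after the data were seen, the calls for midbrain factors (4 of 4), GABAergic genes (5 of 5) and pan-neuronal genes (8 of 8) held, and the other 6 lists had 1 to 6 members of that class, too few for most to pass. The GABAergic call was lost with 5′-most starts (75%) and at a −log10 q of at least 20 (91.7%), and the imprinted call with 5′-most starts (73.3%) and in the list of replicate 2 (93.3%). The forebrain call was lost in the list of replicate 2 (83.3%), with 5′-most starts (77.8%), and with a TSS window of 500 bp or a −log10 q of at least 5 (88.9% each), and at a −log10 q of at least 20 the forebrain share, 61.1%, lay below the 63.4% of other genes.

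The lists of microglia genes, of secreted and terminal genes, of olfactory and vomeronasal receptors and of Hox genes were marked less often than other genes. Of 14 microglia and macrophage genes only Hexb, a lysosomal enzyme gene with 1430 bp covered, was marked (7.14%, adjusted Fisher's exact p = 4.85e-05). Aif1, C1qa and C1qb, genes of microglia and of complement, were unmarked in both replicates. C1qc, chosen after its values were seen, had a peak at its start in replicate 1 only, so the share was 14.3% in that list. Of 25 secreted and terminal genes of non-neural tissues, the keratin genes Krt10 and Krt1 and the muscle creatine kinase gene Ckm were marked (12%, adjusted Fisher's exact p = 3.12e-07). The plasma protein genes Ahsg and Alb and the skeletal muscle actin gene Acta1 were not, although Acta1 had 2032 bp of peaks within 5 kb. The share was 28% with a TSS window of 2.5 kb and 4% with 5′-most starts, and the call held in both. Of 1466 olfactory and vomeronasal receptor genes, 3 were marked (0.205%), with a Fisher's exact p too small to represent. Of the microglia list 1 member had a CpG-rich promoter, and of the secreted and terminal list 0. Among genes CpG-poor at every start, an alternative chosen after the data were seen, these 3 calls held, at 0 of 13, 2 of 24 and 2 of 1465 genes. Hox genes, which pattern the body axis behind the midbrain, were marked at 48.7% (19 of 39, adjusted Fisher's exact p = 0.0490). The Hox call was lost in the lists of replicate 2 (51.3%) and replicate 1 (61.5%), in the pooled list (61.5%) and with a TSS window of 2.5 kb (56.4%). It held at −log10 q minimums of 5 and 20, where the Hox share was 35.9 and 10.3%. Among CpG-rich promoters 58.3% of Hox genes were marked (14 of 24), against 98.9% of other genes, and the call held. Among genes CpG-poor at every start 4 of 10 Hox genes were marked, against 30.8% of other genes, and the list did not pass.

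**Figure D2:**
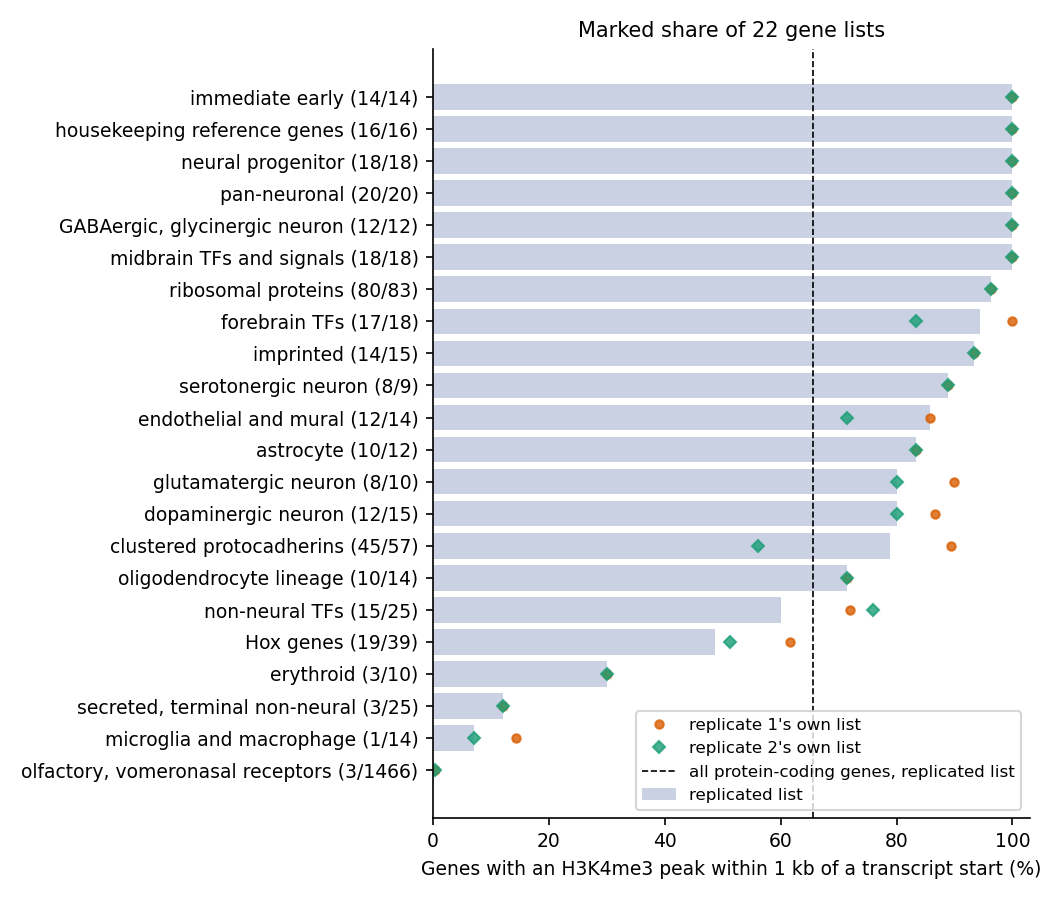
Percent of the protein-coding members of 22 gene lists with an H3K4me3 peak within 1 kb of a transcript start (x axis), as bars for the replicated list with marked and tested members in parentheses. Points show each replicate's own list and the dashed line the share of all protein-coding genes, 65.6%. The clustered protocadherins differ most between the replicates, at 89.5 and 56.1%.

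Several lists of cell types that the midbrain holds did not pass the test. The neuron and glia lists given here had 9 to 15 members, and their shares all lay above the 65.6% of all protein-coding genes. With so few members a raised share can fail to pass, so these results do not show that the lists equal other genes. Of 15 dopaminergic neuron genes 12 were marked (adjusted Fisher's exact p = 0.335). Nr4a2, a transcription factor that specifies these neurons, had 5178 bp covered, the potassium channel gene Kcnj6 4252 bp and Lmx1b 3761 bp. Th, which encodes the rate-limiting enzyme of dopamine synthesis and lies at 142892752 to 142931128 on the minus strand of chromosome 7, had no base of peaks within 5 kb of any of its starts in the replicated list or in either replicate, and Aldh1a1 had none either. Ddc was unmarked in the replicated list but marked in replicate 1 and in the pooled list. Of 9 serotonergic neuron genes 8 were marked (adjusted exact p = 0.231), and the exception was Tph2, the serotonin synthesis enzyme of neurons. Glutamatergic neuron genes were marked at 8 of 10 (adjusted exact p = 0.560), without Slc17a8 and Tbr1, and astrocyte genes at 10 of 12 (adjusted exact p = 0.293), without Gfap and S100b. Oligodendrocyte lineage genes were marked at 10 of 14 (adjusted exact p = 0.783). Olig2, a transcription factor of the lineage, had 7685 bp covered and the precursor receptor gene Pdgfra 4803 bp, and the myelin genes Mag, Mobp and Mog were unmarked. Further myelin genes of the list were chosen after their values were seen. Mbp, with 2337 bp covered, and Cnp, with 2483 bp, were marked. Plp1 was unmarked in the replicated list and in each replicate's own list.

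Endothelial and mural genes were marked at 12 of 14 (adjusted exact p = 0.220), with Esam at 3881 bp and Kdr at 2918 bp, and without Emcn and Tie1. This share passed the test upwards among genes CpG-poor at every start, at 8 of 10. Erythroid genes were marked at 3 of 10 (adjusted exact p = 0.0561), with Epor, Klf1 and Gypa marked, and Alas2, Gata1 and the globin gene Hba-a1 unmarked. With TSS windows of 500 bp and 2.5 kb the erythroid share passed the test downwards, at 20 and 30%. All 10 erythroid genes were CpG-poor at every start, and 30.8% of other such genes were marked. Transcription factors of non-neural lineages were marked at 15 of 25 (adjusted exact p = 0.560). Their share passed the test downwards at a −log10 q of at least 20 (36%), and lay above that of other genes, without passing, in the lists of replicate 1 (72%) and replicate 2 (76%). Hand1, a heart and trophoblast factor, was unmarked in the replicated list although both replicates' own lists marked it. Cdx2, a gut factor, was marked in replicate 1 and in the pooled list only, and the liver factor gene Hnf1a in none of the 4 lists. Clustered protocadherins were marked at 45 of 57 (adjusted exact p = 0.0561), and the 12 unmarked members included Pcdha1, Pcdha7 and 1 of the 2 annotated genes with the symbol Pcdha11, of which the other was marked in both replicates. This share passed the test upwards in the replicate 1 list, in the pooled list, with 5′-most starts and among genes CpG-poor at every start. In the replicate 2 list it was 56.1%, below the 65.1% of other genes, without passing. With a −log10 q of at least 20 it was 19.3% and passed the test downwards.

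Among marked genes, the length of the mark differed between lists. The median covered length was 2268 bp over all marked protein-coding genes. It was 6377.5 bp for GABAergic and glycinergic neuron genes, led by the transcription factor gene Gata3 (10001 bp), the vesicular GABA transporter gene Slc32a1 (9575 bp) and the GABA synthesis gene Gad1 (9417 bp), at 70553072 to 70602014 on chromosome 2. Midbrain regional factors and signals followed at 6025.5 bp, with Gata3, Meis2 and Otx2 covered over the whole 10001 bp window. In replicate 2 Otx2 had 7228 bp covered and Gata3 8921 bp. The midbrain median was 5968.5 bp in replicate 1 and 4332 bp in replicate 2, and the GABAergic median 6875 and 5083 bp. In replicate 2 the midbrain median lay near those of glutamatergic (4209 bp) and pan-neuronal genes (4190 bp). Gata2, Gata3 and Tal2 are in both the midbrain and the GABAergic list, so the medians of both lists rest partly on the same genes. Glutamatergic neuron genes had a median of 5150.5 bp, led by the vesicular glutamate transporter gene Slc17a6 (8918 bp) and the glutamate receptor genes Grin2b (7282 bp) and Gria2 (6201 bp). Pan-neuronal genes had a median of 4703 bp, led by Myt1l (9733 bp), Elavl4 (7491 bp) and the neuronal tubulin gene Tubb3 (6937 bp). Neural progenitor genes had a median of 4545.5 bp, led by Sox2 (6829 bp) and the Notch targets Hes1 (6632 bp) and Hes5 (6462 bp).

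Immediate early genes, which respond to neuronal activity and growth signals, had a median of 4477.5 bp, led by Egr3 (6576 bp), Jun (5957 bp) and Ier2 (5735 bp). Imprinted genes had a median of 4027 bp, led by Peg3 (7424 bp) and by Peg10 and Sgce, a pair of neighbours on chromosome 6 with 5289 bp each. Each of these 7 lists was longer than other marked genes at an adjusted permutation p of 0.0004, which follows from the smallest p that 10000 random lists can give. Against lists matched on CpG number the call for immediate early genes was lost (4477.5 against 3521 bp, adjusted permutation p = 0.101). Astrocyte genes had a median of 3713.5 bp (adjusted permutation p = 0.0101), led by Nfib (9176 bp), Nfia (7017 bp) and the glutamate transporter gene Slc1a2 (5491 bp). The astrocyte call was lost with a window of 10 kb (adjusted permutation p = 0.0568, against 0.00212 to 0.0349 in the other alternatives).

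Hox genes, clustered protocadherins and transcription factors of non-neural lineages carried shorter stretches than other marked genes. Hox genes had a median of 873 bp, with 880 bp in replicate 1 and 408.5 bp in replicate 2, and the longest were Hoxa4 (1388 bp), Hoxa1 (1184 bp) and Hoxd8 (1137 bp). Clustered protocadherins had a median of 1004 bp, with 979 bp in replicate 1 and 660 bp in replicate 2, although Pcdhgc4 (5622 bp), Pcdhgc5 (5284 bp) and Pcdhac2 (4006 bp) lay far above it. Both lists were shorter than other marked genes at an adjusted permutation p of 0.0004, and the protocadherin call was lost with a window of 10 kb, at 2062 bp against 2506 bp for all marked genes. Transcription factors of non-neural lineages had a median of 1462 bp (adjusted permutation p = 0.00468), 1480.5 bp in replicate 1 and 770 bp in replicate 2, with Foxc1 (5682 bp), Tbx3 (3703 bp) and the endothelial factor gene Sox17 (3301 bp) the longest. The 8 longer and 3 shorter calls were all made in each replicate's own list too. The call for non-neural factors was lost at −log10 q minimums of 5 and 20, and with 5′-most starts the median was 2301 bp against 2235 bp for all marked genes.

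The other 7 lists did not pass the test. Dopaminergic neuron genes had a median of 2901.5 bp (adjusted permutation p = 0.143). The median was 3239 bp in replicate 1, where the list passed the test as longer. In replicate 2 it was 1745.5 bp, below the 1994 bp of all marked genes, and the list did not pass. It also lay below, without passing, at a −log10 q of at least 20 (2146 against 2266 bp). Housekeeping genes had a median of 2823.5 bp, led by Ywhaz (5089 bp), Rpl13a (4583 bp) and Tbp (4209 bp). Ribosomal protein genes had a median of 2514.5 bp, led by Rpl7a (5783 bp), Rpl35 (4943 bp) and Rps18 (4812 bp). Serotonergic neuron genes, with Nkx2-2 (4966 bp) and Htr1a (3932 bp), had a median of 2456 bp. The medians of the oligodendrocyte lineage, the forebrain transcription factors and the endothelial and mural genes were 2455.5, 1866 and 1797 bp. In the forebrain list Lhx2 (8861 bp), Bcl11b (8212 bp) and Emx2 (8053 bp) were nonetheless covered over most of the window. The forebrain list passed the test as shorter in replicate 2 (1257 bp) the housekeeping list as longer in replicate 1 (3197 bp), and the ribosomal list as longer with a window of 10 kb (2954.5 bp). Adjusted permutation p for these 7 lists ran from 0.136 to 0.685.

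**Figure D3:**
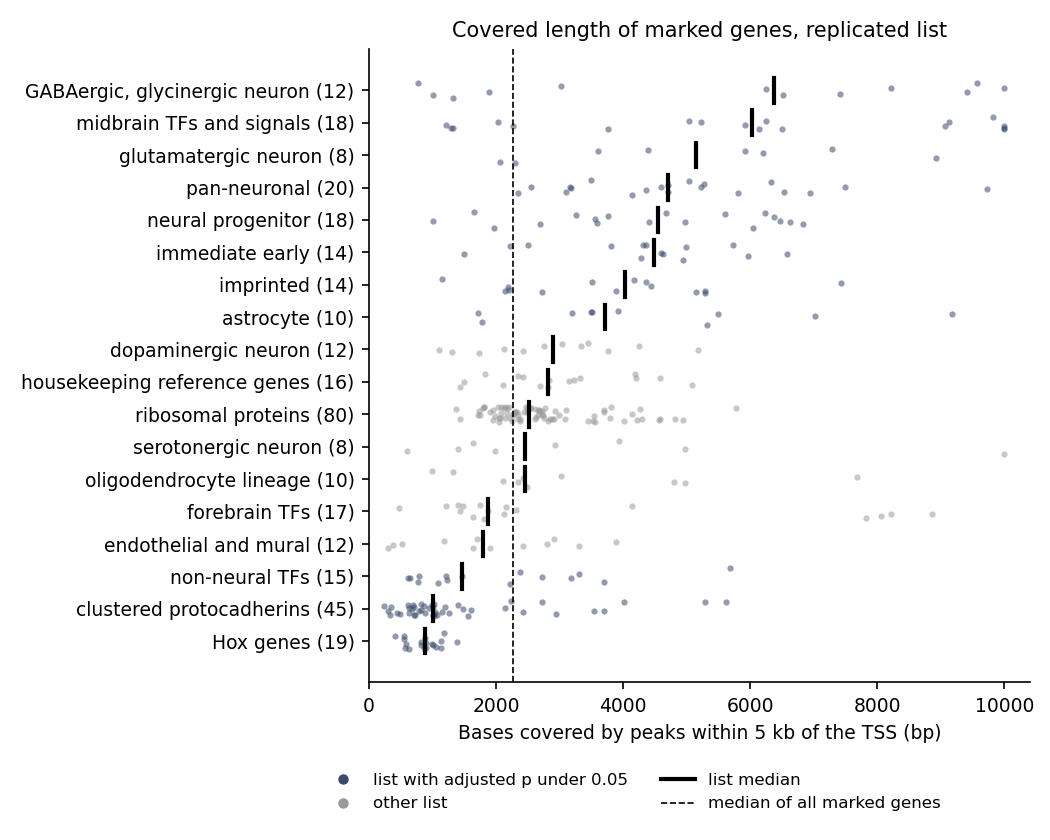
Bases covered by replicated H3K4me3 peaks within 5 kb of the TSS (x axis, bp) for each marked member of 18 gene lists, with the number of marked members in parentheses. Each point is a gene, black bars are list medians, dark points belong to lists with an adjusted permutation p under 0.05, and the dashed line is the median of all marked genes, 2268 bp. List medians run from 873 bp for Hox genes to 6377.5 bp for GABAergic and glycinergic neuron genes.

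The longest domain, 21054 bp at 116052297 to 116073350 on chromosome 2, spanned the 5′ end of Meis2, a homeobox gene. Next were 20252 bp at Lhx9, at 138829612 to 138849863 on chromosome 1, and 18982 bp at 9871201 to 9890182 on chromosome 2. The second of these was nearest to 4930412O13Rik by its centre and also held the starts of Gata3, which specifies GABAergic and serotonergic neurons. The LIM homeobox genes Lhx5 (16647 bp) and Lhx1 (14407 bp), the POU factor genes Pou3f2 (15256 bp) and Pou3f3 (14138 bp), the nuclear receptor genes Nr2f2 (14850 bp) and Nr2f1 (13266 bp), and the Iroquois genes Irx2 (14085 bp) and Irx5 (13557 bp) were among the 20. The others were Mn1, Bahcc1, Nfib, Six3, Tnrc18, En1, Otx2, Myt1l and Runx1t1.

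At most of these genes the domain had a similar length in both replicates, as at Lhx5, with 17121 bp in replicate 1 and 16498 bp in replicate 2. The largest differences were at Nr2f2 (23140 and 8094 bp), Otx2 (20045 and 6490 bp), Six3 (14722 and 5139 bp), Pou3f3 (21263 and 12945 bp) and En1, the engrailed gene of the midbrain and hindbrain (14051 and 8030 bp). No test between replicates was possible for a single gene. Of the 20 genes, 13 were kept when peaks were not merged and 12 when they were merged across 3 kb.

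**Figure D4:**
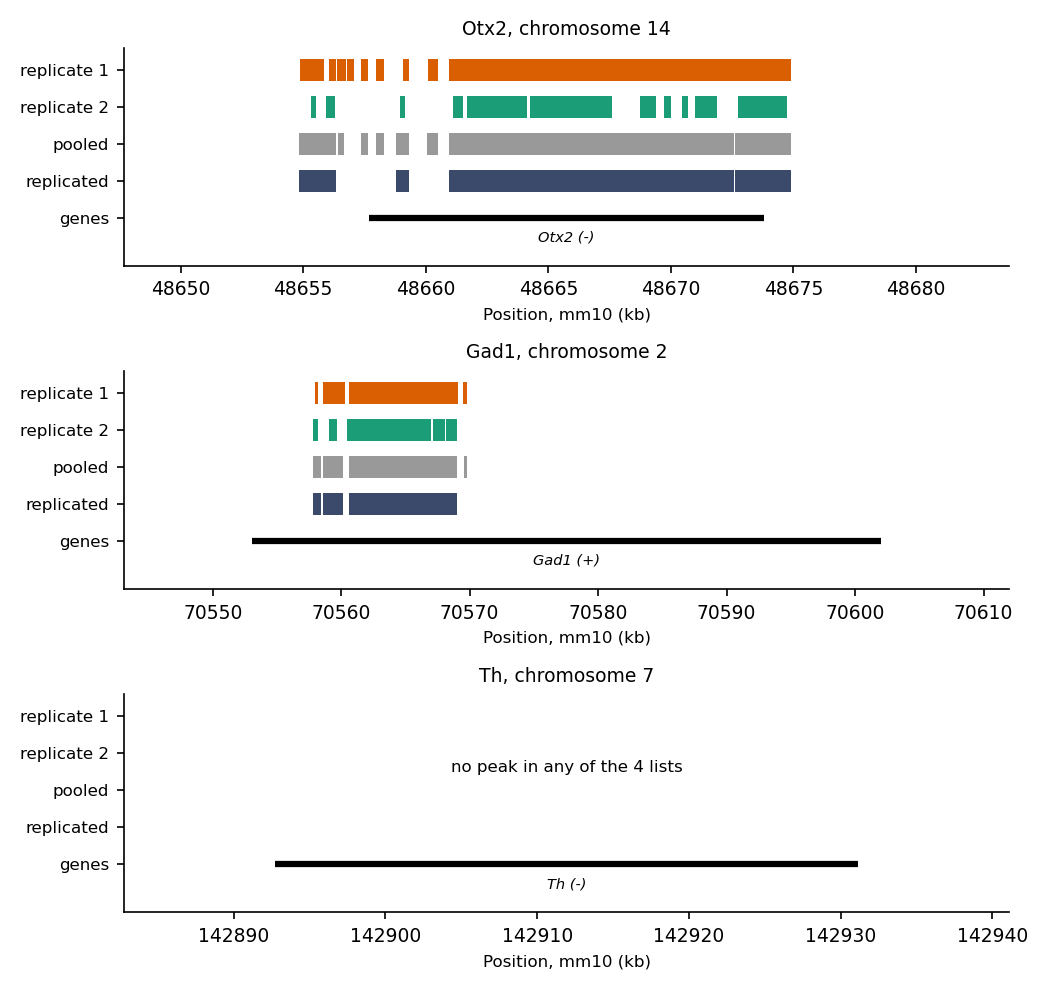
Peaks of the 4 lists (coloured boxes) and the annotated gene with its strand (black line) at Otx2, Gad1 and Th, drawn to scale with 10 kb on either side of each gene; the x axis is the mm10 position in kb. The replicated domain at Otx2 is 13973 bp long and is broken into shorter peaks in replicate 2, and no list has a peak at Th.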

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

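Of 454 alternative values, 377 kept their direction and their side of the threshold or moved by less than the replicate spread, and 77 did not. The 5 alternatives for the number of peaks were judged by a fixed limit wider than that spread, and all 5 are among the 377. All alternatives left the replicate overlap, the share of peaks at a TSS and the CpG contrast past their thresholds, with overlaps from 65.5 to 83.0% and from 70.3 to 99.4%. The 29 values chosen after seeing the data are those in the 4 CpG classes of the X-linked contrast, for any-start CpG classes, for the domain lists of single replicates and for gene lists among genes CpG-poor at every start. No paired analysis was possible because the labels give 1 group. With CpG-rich promoters only, almost every gene was marked, so no list could pass above the others, and shares of 100% for midbrain factors, GABAergic, pan-neuronal, progenitor, forebrain, housekeeping, immediate early and imprinted genes no longer passed, and microglia genes and olfactory receptors (100%, 1 member left in each) and ribosomal genes (98.6%) changed side. Among genes CpG-poor at every start, progenitor, housekeeping and immediate early genes (100%) and forebrain, ribosomal and imprinted genes (66.7%) did not pass, with 1 to 6 members left and too few for most to do so, endothelial (80%) and protocadherin genes (76.9%) now passed, and Hox genes (40%) changed side. The X-linked difference was -0.995 and -2.82 points among CpG-rich and CpG-poor promoters, -0.920 among genes CpG-rich at any start and 1.06 among genes CpG-poor at every start. At a −log10 q of at least 20, the GABAergic call was lost (91.7%), astrocyte (58.3%), endothelial (50%), forebrain (61.1%) and protocadherin genes (19.3%) fell below other genes, the last past the threshold, non-neural factors passed downwards (36%), Hox genes kept their call at 10.3% with too few marked members left to test their length, and covered lengths were 2146 bp for dopaminergic, 2243 bp for serotonergic and 2222 bp for non-neural factor genes. The protein-coding share was 63.4% and the distal share 9.16% there. At a minimum of 5, the calls for forebrain genes (88.9%) and for the length of non-neural factors (1780 bp) were lost, and one-replicate peaks had median widths of 533 and 326 bp. In the replicates' own lists, marked shares ranged from 83.3 to 100% for forebrain, 51.3 to 61.5% for Hox, 72 to 76% for non-neural factor and 56.1 to 89.5% for protocadherin genes, with 93.3% in both for imprinted genes. Covered lengths ranged from 1745.5 to 3239 bp for dopaminergic, 1783.5 to 2621 bp for serotonergic, 1257 to 2233 bp for forebrain, 408.5 to 880 bp for Hox, 770 to 1480.5 bp for non-neural factor, 660 to 979 bp for protocadherin and 2607.5 to 3197 bp for housekeeping genes. The pooled list gave 61.5% for Hox, 72% for non-neural factor and 87.7% for protocadherin genes. With a TSS window of 2.5 kb the shares were 56.4% for Hox, 68% for non-neural factor, 30% for erythroid and 66.7% for all protein-coding genes, and with 500 bp they were 20% for erythroid and 88.9% for forebrain genes. With 5′-most starts they were 75% for GABAergic, 77.8% for forebrain, 73.3% for imprinted, 78.9% for protocadherin and 62.1% for all protein-coding genes, the non-neural factor length was 2301 bp and the distal share 24.8%. Distal limits of 2.5 and 10 kb gave 21.9 and 11.5%. A covered-length window of 10 kb gave 3713.5 bp for astrocyte, 2455.5 bp for oligodendrocyte, 2062 bp for protocadherin and 2954.5 bp for ribosomal genes, of which the ribosomal list now passed as longer, and one of 2.5 kb gave 2161.5 bp for serotonergic genes. Of the 20 genes at the longest domains, 13 were kept without merging and 12 with merging across 3 kb. Stricter minimums and narrower windows leave fewer peaks by construction, and for the other changes the cause was not tested. Depth limits how weak a peak each list can hold, and it is unknown here.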

Other observations

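Chosen after the result was seen were the counts of list members among the longest 5% of marked genes and of homeobox genes and the tests on unmarked neural genes, on annotated starts, and the replicate ratios of lists other than the midbrain and forebrain factors. The homeobox symbols and the CpG test on unmarked genes were also redefined after a first result. The longest 5% of marked genes, 720 genes with at least 5007 bp covered, held 12 of the 18 midbrain regional factors and signals, 7 of the 12 GABAergic and glycinergic neuron genes and 9 of the 20 pan-neuronal genes. They held 4 of the 17 marked forebrain transcription factors and 1 of the 12 marked dopaminergic neuron genes. None of the 19 marked Hox, 12 marked endothelial or 3 marked erythroid genes was among them. In lists this small, counts of 0 or 1 do not lie clearly below 5%. Among genes that do not encode proteins, 34.9% of antisense genes (1034 of 2959) and 14.6% of lincRNA genes (853 of 5854) were marked. Processed pseudogenes were marked at 1.85% (184 of 9940). Antisense genes can share a promoter region with a neighbour, so their share is not that of separate promoters. On the Y chromosome 4 of 183 protein-coding genes were marked.

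Of 143 marked genes of homeobox families, picked by symbol after the longest domains were seen, 39 were in the longest 5%. With the 22 marked genes at the 20 longest domains left out the share was 21.2% of 132, against 4.70% of other marked genes. Of the 19 marked Hox genes 0 were in the longest 5%, too few genes for that count alone to show a lower share. A Fisher's exact test of these shares was run and is not reported, because the family was picked from these data, and the shares were not matched on CpG number.

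Long and short stretches of the mark could follow the CpG content around the TSS. Midbrain factors had a median of 305 CpG dinucleotides within 5 kb of the 5′-most start, against 181 for all marked genes. Against lists matched on that number, 7 of the 8 long lists kept an adjusted permutation p under 0.05, and 3 of the 3 short lists did. Immediate early genes were the exception at 0.101. Matched medians for midbrain factors (3547.75 bp) and progenitor genes (3212.5 bp) lay above the 2268 bp of all marked genes, so CpG number went with part of their length. For pan-neuronal and glutamatergic genes they were 2272 and 2283.5 bp. Covered length took the start with the most bases, which can lie away from the 5′-most start. The match therefore cannot exclude CpG content at the covered start. For the long lists the number of annotated starts per gene was argued against, since 8 of the 8 kept their call with the 5′-most start only. Of the short lists the non-neural factors did not keep theirs (2301 against 2235 bp). Forebrain transcription factors, not called before matching, were shorter than their matched lists (1866 against 3626 bp, adjusted permutation p = 0.000514). What remains open is whether CpG content at the covered start, cell composition or regional identity sets these lengths, and no biological explanation was tested.

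Of 108 genes in the 8 lists of neurons, progenitors, astrocytes and oligodendrocytes, 12 had no replicated peak at a TSS: Aldh1a1, Ddc, Gfap, Mag, Mobp, Mog, Plp1, S100b, Slc17a8, Tbr1, Th and Tph2. The rule for replicated peaks does not account for most of them, because only 2, Ddc and Tbr1, had a peak at a TSS in another list. Starts misplaced by up to 2.5 kb are argued against, because 0 had a replicated peak within 2.5 kb of a start. Starts that lie further away were not tested. Within 5 kb of a start Gfap had 703 bp of replicated peaks and Mog 258 bp. CpG-poor promoters stay open as an explanation: 100% of the 12 were CpG-poor at every annotated start, against 30.2% of the 96 marked members (Fisher's exact p = 2.83e-06). That test says little, because 98.7% of all protein-coding genes CpG-rich at any start were marked, so an unmarked gene is nearly always CpG-poor. The CpG-poor members of these lists were marked at 70.7% (29 of 41), against 30.7% of other such genes (Fisher's exact p = 1.66e-07). A CpG-poor promoter alone thus did not leave most members unmarked. Expression in few cells of the tissue, or after birth, may leave too little signal to be called; that was not tested, as no expression data were used.

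Replicate 1 had longer or additional peaks at some groups of genes, and a candidate explanation is weak signal near the calling threshold. Of the protocadherin genes marked in replicate 1, 39.2% had no replicate 2 peak, within the 95% range of 25.5 to 47.1% for lists of genes matched on replicate 1 signal value, and the forebrain factors' ratio of covered length, 1.51, was within its range of 1.18 to 1.59 for lists matched on signal value and covered length. For midbrain regional factors the ratio of 1.43 lay above the matched range of 1.13 to 1.37, although over 18 lists the adjusted permutation p was 0.0780. The signal value matched was the highest within 1 kb of a start, and covered length reaches 5 kb from it. Weak signal in the outer parts was not matched, so the test cannot decide on it there. Ratios also lay above their matched ranges for dopaminergic neuron genes (1.48, adjusted permutation p = 0.0144), endothelial and mural genes (1.67, 0.0780), oligodendrocyte lineage genes (1.48, 0.101) and protocadherins marked in both replicates (1.89, 0.101), of which only the dopaminergic list passed the correction. No test compared the lists with each other, and a difference in depth or in the tissue taken for the replicates stays open and untested.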
